A study of Mus musculus with 10 samples.

How the data were processed

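Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in v6.5 mouse embryonic stem cells kept for 4 passages in 2i/LIF medium, per the labels' protocols. The acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled in 2 libraries of cells depleted of the SUMO-conjugating enzyme Ubc9 and in 2 libraries of the isogenic Ubc9 control line. Depletion used a TET-OFF system and 72 h of doxycycline. No doxycycline time is recorded for the control libraries. The small modifier SUMO1 was profiled in 1 library of wild-type cells. Cells were fixed with 1% formaldehyde for 10 min and chromatin was sheared to 200 to 800 bp. The 5 input samples of the series have no peak list of their own and were not analysed here.

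Reads were converted with bcl2fastq 2.17.1.14, aligned to mm10 with Bowtie2 and passed to MACS 1.4.2-157 for peak calling, per the submitters' processing notes. The notes give no Bowtie2 version. For each of the 5 immunoprecipitated libraries, the authors deposited a list of peaks with a score for each peak. The score was read as the peak caller's own measure of confidence, which grows with sequencing depth. In the main results it was therefore not compared between libraries and served only to rank the peaks within a list. The alternative setting with a score of at least 100 puts the same threshold on all lists. Median scores were lower in the depleted lists, so that setting can remove more depleted than control peaks. Read depth is unknown, since the peak lists hold no read counts. Intervals in the text are exact (Clopper-Pearson or conditional) 95% intervals and cover counting error only.

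Peaks on chromosomes 1 to 19, X and Y were used. The H3K27ac peaks of the 4 libraries were merged where they overlapped by at least 1 bp, which gave 49094 regions. A region counted for a library when a peak of that library lay in it. A region or gene is called depletion-only when it had a peak in both depleted libraries and in neither control library, and control-only in the opposite case. The gene table (GRCm38.p6, the assembly that mm10 stands for) gives the start and end of each gene without strand or transcripts. The planned test of promoters was replaced for this reason. A gene counted as marked when a peak overlapped 1000 bp on either side of either annotated gene end, so a mark can lie at the 3' end of a gene, and genes that share an end share a peak. The table holds 49943 genes on these chromosomes, of which 21887 are protein-coding.

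With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.33. Counts of regions and genes are therefore set beside the same counts for the other groupings among the 3 ways to split the 4 libraries into pairs. Proportions of regions or genes were compared with Fisher's exact test, two-sided, with regions or genes as the unit and not samples. The 18 gene lists were tested against all coding genes and, for regions, against all merged regions. The members' regions were those within 50 kb of a member. The p-values were adjusted by the Benjamini-Hochberg method over 36 tests of gene ends, 36 tests of nearby regions and 18 tests of SUMO1. The overlap of SUMO1 peaks with H3K27ac was compared with 1000 circular shifts of the SUMO1 peaks along their chromosomes, and 0.002 is the smallest p these shifts can give. Similarity of peak lists was measured by the base-pair Jaccard index.

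The lists cover 2-cell-stage genes (34 of 38 names matched the gene table), naive pluripotency genes (30), post-implantation epiblast genes (20), trophoblast genes (23), primitive endoderm genes (21), germ-layer regulators (22), germline genes (25), SUMO pathway genes (20) and heterochromatin and silencing factors (25). They also cover linker histone genes (10), core histone genes (58), ribosomal protein genes (84), Zfp-named zinc finger genes (394), imprinted genes (22 of 26 names matched), p53 targets (18), interferon-response genes (18 of 21 names matched), fibroblast markers for feeder cells (19) and housekeeping genes (17).

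Groups, comparisons, tests, gene lists and the rule for named genes were set before the data were examined. The rule names a fixed set of genes in every library, and the 10 depletion-only and 10 control-only genes whose best peaks ranked highest within their own lists. It also names up to 4 members per list and class, 5 regions per class away from gene ends and the 10 SUMO1 peaks of highest score. Genes named outside this rule were chosen after their values were seen, and the text says so where they appear.

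Alternative settings chosen at the same time were lists of an equal number of peaks, a score of at least 100, an overlap of 50% of the shorter interval, merging of peaks up to 1000 bp apart, windows of 2500 bp, marked genes as background, a neighbourhood of 20 kb, uniform random positions, windows of 1000 bp at region midpoints, a check of pairing by replicate number, and leaving out each H3K27ac library in turn. Lists of equal covered length, a rotation test and peaks widened to their merged regions were chosen after seeing the data. The rotation test turns the classes of genes or regions around the genome in their order, so that neighbours keep their grouping.

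The procedure was tested on simulated peak lists. It recovered 5000 of 5000 simulated depletion-only and 8000 of 8000 control-only regions among 30000, and a simulated overlap of 25% for 8000 SUMO1 peaks. The simulated sites lay too far apart to touch and no peak was missed, so this recovery checks the counting alone. Unequal peak recovery and neighbouring peaks bridged by a wide one were not simulated. A seeded list among 21887 genes was called and 0 null lists were. When class members were placed in clusters, 25 of 100 null lists had p under 0.05 by Fisher's exact test and 1 of 100 by the rotation test, so rotation values are given beside Fisher's. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.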

Results

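H3K27ac, a histone mark of active promoters and enhancers, was mapped in mouse embryonic stem cells after loss of Ubc9, the enzyme that attaches SUMO proteins to their targets. The 2 depleted libraries were compared with 2 libraries of the isogenic control line, and SUMO1 itself was mapped in 1 library of wild-type cells. The depleted lists held 38561 and 27349 peaks on chromosomes 1 to 19, X and Y, and the control lists held 29192 and 34106 (means 32955 ± 7928 and 31649 ± 3475, SD, n = 2). Depleted peaks were narrower, with median widths of 725 and 892 bp against 1632 and 1219 bp. Depleted lists covered 36.8 ± 5.30 Mb and control lists 63.5 ± 4.18 Mb (SD, n = 2). The SUMO1 list held 8718 peaks over 3.54 Mb, with a median width of 377 bp. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical only. Read depth is unknown.

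Ube2i, the gene for Ubc9 (chromosome 17, 25260510 to 25275799, mm10), had an H3K27ac peak within 1 kb of a gene end in both control libraries and in depleted replicate 2, and none in depleted replicate 1. The mark at this gene does not measure the amount of Ubc9 protein, so it does not check the depletion. Sumo1 and Sumo2 were marked in all 4 libraries. The same held for the pluripotency factors Pou5f1, Nanog, Sox2, Klf4 and Zfp42, for the cell-cycle inhibitor Cdkn1a, for the germline gene Dazl and for Actb. Prdm14, a regulator of naive pluripotency and the germline, lacked a peak in depleted replicate 2 alone. Its best peak ranked at the 17.4 percentile of the list in depleted replicate 1, against 80.5 and 86.3 in the controls. Esrrb, an orphan nuclear receptor of naive cells, was marked in both control libraries and in neither depleted library. Its control peaks ranked at the 31.2 and 30.5 percentile. This is the lowest of 4 equal groups of genes by control peak rank, in which 47.9% of genes were control-only. Gata6 of the primitive endoderm, Cdx2 of the trophoblast and Zfp352 had a peak in none of the 4 libraries.

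The first comparison asked which genes gained H3K27ac without Ubc9, and the clearest group was that of the 2-cell embryo. Of 34 genes expressed at that stage, 22 and 22 were marked in the depleted libraries against 6 and 9 in the control libraries. A peak in both depleted libraries and in neither control was present at 14 of them (41.2%), compared with 0.553% of all 21887 coding genes. These included Usp17le (chromosome 7, 104767961 to 104777470) and Usp17lb, which belong to a family of deubiquitinating enzymes, Tdpoz1 (chromosome 3, 93669333 to 93676283) and BB287469 (chromosome 12, 87816577 to 87820676). The other 10, named after their values were seen, were Pramel17, Pramel11, Usp17ld, Usp17lc, Gm6763, Gm4340, Arg2, Gm8300, Gm2022 and Tcstv3. Zscan4c and Zscan4d, which mark the 2-cell-like state of stem cell cultures, were marked in all 4 libraries. Their best peaks ranked at the 96.6 and 97.8 percentile of the depleted lists on average, and at the 48.8 and 29.8 percentile of the control lists. Duxf3 had a peak in depleted replicate 1, at the 85.6 percentile, and in control replicate 2, at the 7.59 percentile. Zfp750 was the only member of the list with peaks in both controls alone.

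The 2-cell-stage list was the only call among 36 tests of gene ends (odds ratio 142, 95% interval 64.4 to 304, p = 1.45e-23, adjusted p = 5.23e-22, Fisher's exact test). Its genes lie in clusters, and a permutation test that rotates gene classes around the genome gave p = 9.14e-05, the smallest it can give, and an adjusted p of 0.00329. With lists of equal covered length, chosen after seeing the data, the odds ratio was 15.0 (adjusted p = 1.06e-10, Fisher's exact test). It was 68.2 with windows of 2500 bp and 58.5 without depleted replicate 2, and 95.1 with 11 depletion-only members when peaks were widened to their merged regions.

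A stretch of chromosome 12 around Gm8300, BB287469 and Gm2022, chosen after its values were seen, shows the pattern at a repeated gene cluster. The stretch from 87494316 to 88349682 held 129 and 105 peaks in the depleted libraries and 22 and 31 in the control libraries. The peaks covered 177 and 161 kb in the depleted libraries against 46.8 and 55.1 kb in the controls. Of its 18 coding genes, 7 were marked in both depleted libraries alone and 0 in both control libraries alone. Repeats and mappability were not examined, so peaks over near-identical copies need not be separate sites. Gm10264, at the right-hand edge, was also among the 10 highest-ranking depletion-only genes of the genome.

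**Figure D1:**
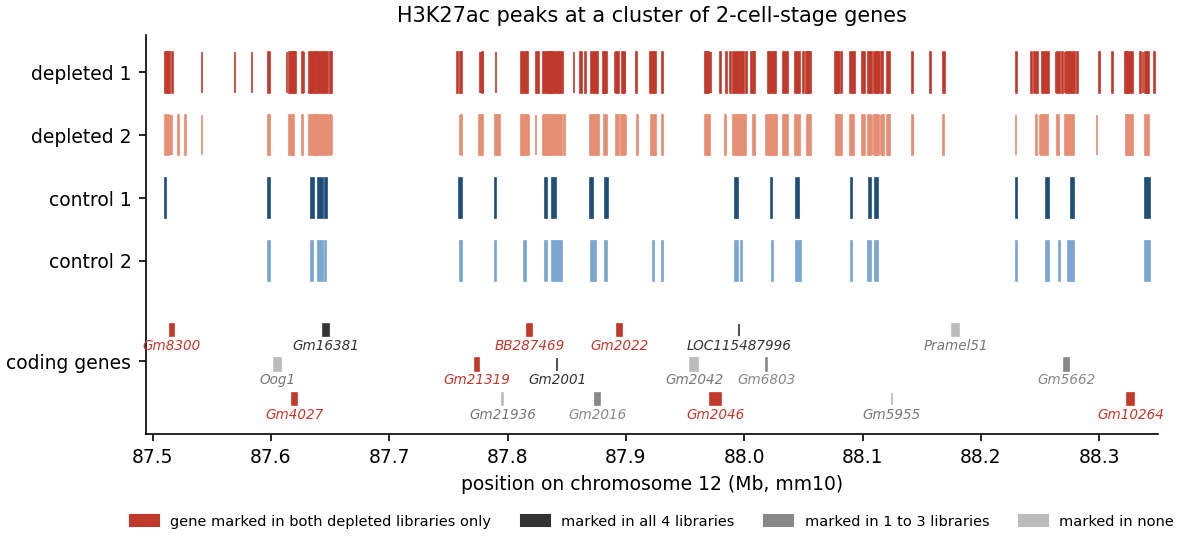
H3K27ac peaks (bars) of the 4 libraries along chromosome 12 (x axis, position in Mb, mm10), with the coding genes below, coloured by the libraries that marked them. The depleted libraries hold 129 and 105 peaks and the control libraries 22 and 31, and 7 of the 18 genes are marked in both depleted libraries alone.

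Over the whole genome, 121 coding genes were depletion-only and 1610 control-only, while 5411 were marked in all 4 libraries. The depletion-only genes with the highest-ranking peaks were Sult2a3, a sulfotransferase gene (chromosome 7, 14067555 to 14123048), Usp17le, the matrix metalloproteinase genes Mmp1b and Mmp12 (chromosome 9), Rdh16, a retinol dehydrogenase gene, LOC115489542, the vomeronasal receptor gene Vmn1r43, the zinc finger gene Zkscan4, Usp17lb and Gm10264. Of these, Rdh16, LOC115489542, Mmp12, Zkscan4, Usp17lb and Gm10264 stayed depletion-only when each peak was widened to its merged region. The control-only genes that ranked highest were Acsbg2, Arnt2, Cenpx, Cga, Dcst2, Efnb3, Fabp12, Ffar2, Flnb and Gabbr2. These shared the top rank with further genes (16 tied), and 0 of the 16 stayed control-only with widened peaks. The highest-ranking genes that stayed, named after their values were seen, included Otx2 (chromosome 14, 48656781 to 48667644) and Gsc (chromosome 12, 104471209 to 104473236), which encode homeodomain factors of the epiblast and gastrula, and Cdo1, Cbr3 and Dusp16.

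As merged regions, 5242 of 49094 (10.7%) were depletion-only and 8181 (16.7%) control-only, and 12442 (25.3%) were found in all 4 libraries. The other 2 splits of the 4 libraries gave 245 and 132 regions, and 524 and 71. For genes they gave 48 and 12, and 114 and 7. The 114 genes, marked in depleted replicate 1 and control replicate 2 alone, came near the 121 depletion-only genes in number. With lists of an equal number of peaks, the other splits gave at most 53 genes, against 125 depletion-only genes. The base-pair Jaccard index was 0.731 for the control pair and 0.568 for the depleted pair, against 0.301 to 0.364 between groups. Depletion-only regions lay at coding gene ends in 3.89% of cases (204) and control-only regions in 19.9% (1631), an odds ratio of 0.163 (95% interval 0.139 to 0.189, p = 2.66e-178, Fisher's exact test).

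The excess of control-only genes and regions held with lists of an equal number of peaks (125 depletion-only and 1840 control-only genes, 4621 and 7817 regions). With a score of at least 100 there were 90 and 1818 genes, and 2596 and 7047 regions. Median scores were 130 and 111 in the depleted and 218 and 206 in the control lists, so this cut can favour the excess by itself. With lists of equal covered length, which kept 60.8% and 100% of the depleted and 25.4% and 27.7% of the control peaks, the balance turned, and there were 1379 depletion-only and 198 control-only genes, 8601 depletion-only and 710 control-only regions, and an odds ratio at gene ends of 1.08 (p = 0.515, Fisher's exact test). Windows of 2500 bp gave 185 depletion-only and 1649 control-only genes. Without depleted replicate 1, there were 8722 depletion-only and 12085 control-only regions, 161 depletion-only and 3403 control-only genes, and the odds ratio was 0.103. Without depleted replicate 2, the region balance turned, with 13752 depletion-only and 8708 control-only regions, while 272 genes were depletion-only and 1732 control-only. Without control replicate 1, there were 14572 control-only regions.

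**Figure D2:**
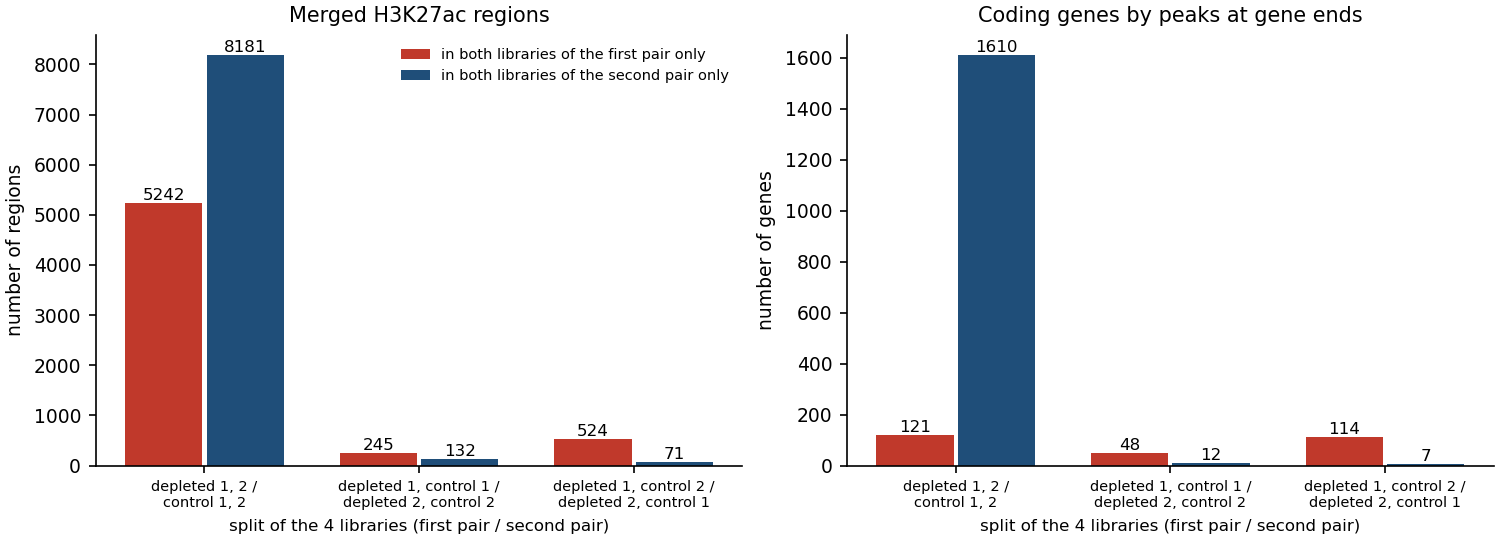
Number of merged H3K27ac regions (left, y axis) and of coding genes with a peak at a gene end (right, y axis) found in both libraries of a pair and in neither of the other pair, for the 3 ways to split the 4 libraries (x axis). The split by group gives 5242 and 8181 regions and 121 and 1610 genes. The other splits give at most 524 regions and 114 genes, so the 121 depletion-only genes come near the count of a mixed split.

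Genes of naive pluripotency were mostly marked in both groups, with some control-only members. Of 30, 28 and 28 were marked in the control libraries and 22 and 19 in the depleted libraries. The 6 control-only members (20.0%, against 7.36% of all coding genes) were Tcl1 (chromosome 12, 105216753 to 105222737), Tdh, the threonine dehydrogenase gene, Nr0b1, an orphan nuclear receptor gene on chromosome X, and Dppa3 (chromosome 6, 122626424 to 122630271), a maternal factor gene, with Utf1, named after its values were seen, and Esrrb. The odds ratio was 3.16 (95% interval 1.05 to 7.94), with p = 0.0202 and an adjusted p of 0.189 (Fisher's exact test), and p = 0.0407 and adjusted p = 0.488 by rotation. The list passed the threshold of Fisher's exact test with lists of equal peak number or with a score of at least 100, with 8 control-only members in either case, and 2 members were control-only at equal covered length.

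The other lineage lists had few members in either class. Control-only members were 3 of 20 post-implantation epiblast genes (Otx2, Etv4 and Lefty2), 2 of 23 trophoblast genes (Ets2 and Gata3), 1 of 21 primitive endoderm genes (Lama1), 2 of 22 germ-layer regulators (Gsc and Nes) and 3 of 25 germline genes (Rpl10l, Hormad1 and Smc1b). None of these 5 lists had a depletion-only member. Among 19 fibroblast markers, which would follow feeder cells, Col6a1 and Fbn1 were depletion-only (p = 0.00487, adjusted p = 0.0877, Fisher's exact test) and Vim was control-only. With windows of 2500 bp, or with marked genes as background, the fibroblast list passed the threshold.

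Of 20 genes of the SUMO pathway, 18 and 17 were marked in the depleted libraries and 19 and 19 in the controls, with 0 in either class. Pias4, a SUMO ligase gene, was marked in both controls and lacked a peak in depleted replicate 2, as Ube2i did in depleted replicate 1. Chaf1b, a chromatin assembly factor gene, was the control-only member among 25 heterochromatin and silencing factors, and H1f5 the one among 10 linker histone genes. Ribosomal protein genes had 2 control-only members of 84 (Rps27l and Rpl10l), imprinted genes 1 of 22 (Plagl1) and p53 targets 1 of 18 (Plk2). The 58 core histone genes (p = 0.0210 for fewer control-only members than other genes, adjusted p = 0.189, Fisher's exact test), 18 interferon-response genes and 17 housekeeping genes had 0 members in either class. Of 394 zinc finger genes with Zfp names, Zfp992 and Zfp790 were depletion-only and 29 (7.36%) were control-only, led by Zfp397, Zfp750, Zfp607b and Zfp647. With marked genes as background, the core histone, ribosomal protein and zinc finger lists passed the threshold for a lower control-only share than other marked genes. At equal covered length, the zinc finger list passed for its depletion-only share.

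**Figure D3:**
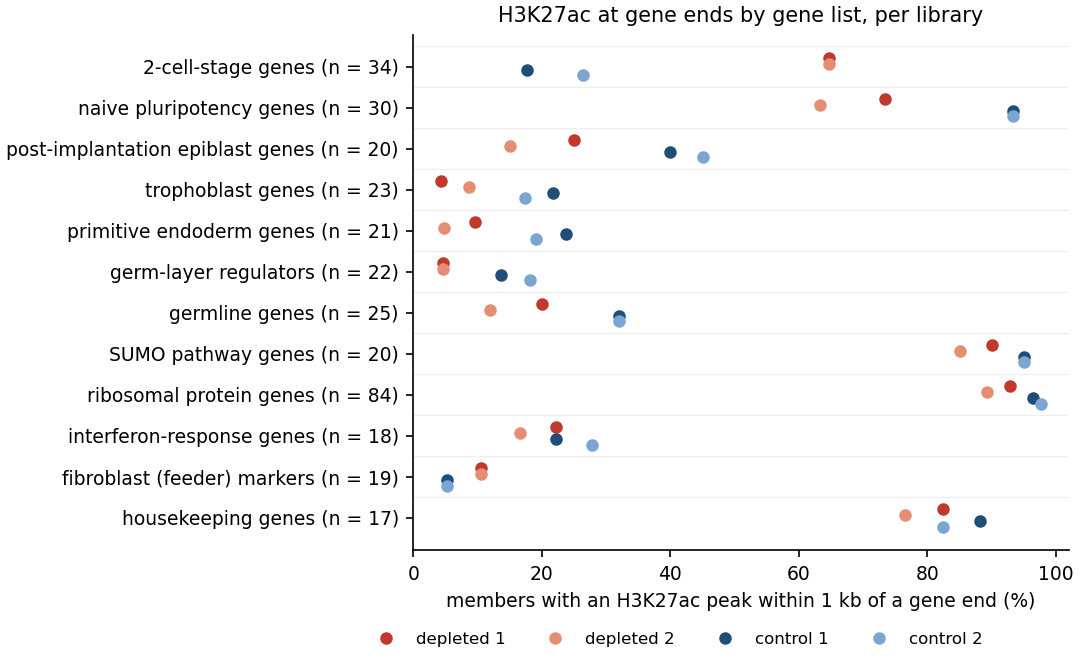
Percentage of the members of 12 gene lists with an H3K27ac peak within 1 kb of a gene end (x axis), 1 point per library, with the list size n on the y axis. The 2-cell-stage genes are marked in 64.7% and 64.7% in the depleted libraries against 17.6% and 26.5% in the controls, and the naive pluripotency genes in 73.3% and 63.3% against 93.3% and 93.3%.

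Regions within 50 kb of list members were compared next, to take in enhancers. Near 2-cell-stage genes, 82 of 283 regions (29.0%, against 10.7% of all regions) were depletion-only, and 5 (1.77%, against 16.7%) were control-only. Near naive pluripotency genes, 4 of 224 (1.79%) were depletion-only and 56 control-only. Near post-implantation epiblast genes, 27 of 82 (32.9%) were control-only. Near ribosomal protein genes, 26 of 545 (4.77%) were depletion-only. The adjusted p by rotation was 0.000733 and 0.00440 for the 2-cell-stage classes, 0.000733 for depletion-only regions near naive genes, 0.0381 for the epiblast and 0.00196 for the ribosomal list. Control-only regions near naive genes had an adjusted p of 0.00620 by Fisher's exact test and 0.0640 by rotation.

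For depletion-only regions near 2-cell-stage genes, the odds ratio of 3.45 was 8.16 without depleted replicate 1, 7.33 without depleted replicate 2, 6.79 with a score of at least 100 and 1.80 at equal covered length, and the call held in each case. For control-only regions near these genes, 0.0894 became 0.142 without depleted replicate 1, 0.167 with a score of at least 100 and 0 at equal covered length or within 20 kb. Near naive genes, the depletion-only odds ratio of 0.151 became 0.237 without control replicate 2, 0.271 at equal covered length and 0.0913 with peaks up to 1000 bp apart merged. The control-only call near naive genes ended without depleted replicate 1 (odds ratio 1.31, adjusted p = 0.0975, Fisher's exact test), with merged peaks (1.38) and at equal covered length (2.60). At equal covered length, the epiblast odds ratio of 2.46 was 4.49 and the ribosomal one of 0.416 was 0.626.

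In all, 18 of 36 tests of nearby regions passed at an adjusted p under 0.05 by Fisher's exact test and 5 by rotation, the 5 just given. Trophoblast (32.1%), primitive endoderm (32.9%) and germline genes (31.5%) were among those with more control-only regions by Fisher's exact test whose adjusted p by rotation was 0.0883, 0.0559 and 0.0559. With lists of an equal number of peaks, 11 tests passed, and the primitive endoderm list had 0 control-only regions nearby at equal covered length (p = 1, Fisher's exact test), where 710 were left in the genome.

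Away from gene ends, the depletion-only regions of highest rank lay on chromosome 3 at 94207780 to 94212675 and at 94131806 to 94137173, next to the pseudogenes Spopfm3 and Gm9131, and on chromosome 11 at 30316056 to 30321238 in the non-coding gene Gm40820. A further such region lay on chromosome 14 at 18536070 to 18542161 in Gm32587, and another on chromosome 10 at 83372987 to 83382428, 4152 bp from D10Wsu102e. The control-only regions of highest rank lay on chromosome 19 at 55711027 to 55717224, on chromosome 17 at 84349541 to 84357783 in Thada and on chromosome 5 at 134368650 to 134373276 in Gtf2ird1. On chromosome 4, they lay at 99667259 to 99672964, 8588 bp from Foxd3, a transcription factor gene of pluripotent cells, and at 84017046 to 84023749.

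The SUMO1 library addressed where SUMO1 sits relative to active chromatin. Its highest-scoring peaks lay on chromosome Y near Gm52481 (90733257 to 90736467 and 90737354 to 90740718) and Gm33272, on chromosome 5 near the pseudogene Gm2420 (32712141 to 32714181) and at the ribosomal RNA pseudogene Rn18s-rs5 (chromosome 17, 39842972 to 39848851). Further ones lay near Rny3 on chromosome 6, at the tRNA genes n-TPagg4 and n-TTtgt3 on chromosome 14, at 3 tRNA genes on chromosome 11, in Zfp982 (chromosome 4, 147471254 to 147473332) and in Exd1 on chromosome 2. The peak in Zfp982 and the highest-scoring one on chromosome Y, at 90733257, carried H3K27ac in both depleted libraries and in neither control. The nearby chromosome Y peak at 90737354 carried it in all 4 libraries, and the one near Gm33272 in both depleted libraries and control replicate 1. Repeats and mappability were not examined at these peaks. Of 8718 SUMO1 peaks, 1867 (21.4%, 95% interval 20.6 to 22.3) overlapped H3K27ac of both control libraries, compared with a mean of 2.67% after 1000 shifts (p = 0.002, the smallest they can give, permutation test). This was 8.03 times the shifted mean. At equal covered length, the values were 9.61% and 1.30%. A coding gene end lay within reach of 1473 peaks (16.9%), and 5849 (67.1%) had no H3K27ac in any library.

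Across libraries, 23.4% and 18.8% of SUMO1 peaks carried H3K27ac in the depleted libraries and 23.7% and 23.8% in the controls (means 21.1 ± 3.28 and 23.8 ± 0.105, SD, n = 2). The difference of -2.67 percentage points was within the spread of the depleted pair, and at equal covered length it was 8.29. It was -4.98 without depleted replicate 1 and -0.350 without depleted replicate 2. SUMO1 was measured in unmodified cells, so the overlap sets the depleted libraries beside SUMO1 as it was with Ubc9 present.

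Germline genes stood out among the genes with SUMO1. Of 25, 10 had a SUMO1 peak (40.0%, 95% interval 21.1 to 61.3, against 7.18% of all coding genes). Ddx4 (chromosome 13, 112598333 to 112652633), the Vasa helicase gene, and the meiotic genes Meioc and Sycp2 carried SUMO1 without H3K27ac in any library, and Dazl (chromosome 17, 50279393 to 50293620) carried both. The odds ratio was 8.67 (95% interval 3.48 to 20.7, p = 4.24e-06, adjusted p = 7.64e-05, Fisher's exact test), with p = 9.14e-05, the smallest it can give, and adjusted p = 0.00164 by rotation. With a score of at least 100, the odds ratio was 13.1.

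No other of the 18 lists passed for SUMO1. Members with a SUMO1 peak were Pou3f1, Etv4, Zic2 and Cdh2 among post-implantation epiblast genes (4 of 20, adjusted p = 0.412), and Mixl1, Nes, Mesp1 and Neurog1 among germ-layer regulators (4 of 22, adjusted p = 0.412, Fisher's exact test). In the SUMO pathway they were Pias4, Uba2 and Sumo3 (3 of 20), and among silencing factors E2f6, Hdac2 and Kdm1a (3 of 25). Imprinted genes had Nap1l5, Impact and Peg10 (3 of 22), and primitive endoderm genes Col4a1 and Col4a2, which share an end (2 of 21). There was 1 each among linker histone genes (H1f10, of 10), core histone genes (H4c8, of 58), p53 targets (Gdf15, of 18) and interferon-response genes (Stat2, of 18). Ribosomal protein genes had 8 of 84, among them Rpl36 and Rpl26, and Zfp-named genes 27 of 394, led by Zfp541, Zfp280d, Zfp455 and Zfp992. The 2-cell-stage (0 of 34), naive pluripotency (0 of 30), trophoblast (0 of 23), fibroblast (0 of 19) and housekeeping lists (0 of 17) had 0. With marked genes as background, the Zfp-named list passed as well, but for a lower share with SUMO1 than other marked genes.

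**Figure D4:**
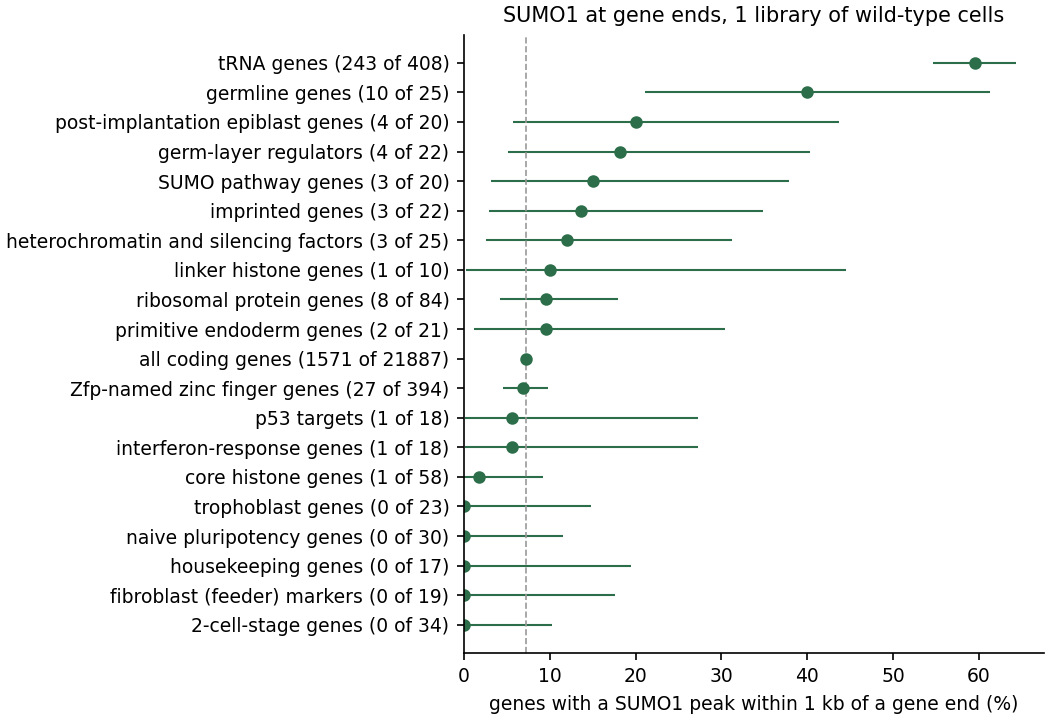
Percentage of genes with a SUMO1 peak within 1 kb of a gene end (x axis) for the 18 lists, all coding genes and tRNA genes, the last chosen after their values were seen, with exact 95% intervals (lines, counting error only) and all coding genes as the dashed line. Germline genes reach 40.0% and tRNA genes 59.6%, against 7.18% of all coding genes.

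SUMO1 was also compared between the classes of H3K27ac regions. It lay on 9.73% of regions found in all 4 libraries, on 5.53% of depletion-only regions (290, 95% interval 4.93 to 6.19) and on 3.79% of control-only regions (310, 3.39 to 4.23). The odds ratio of depletion-only against control-only regions was 1.49 (95% interval 1.26 to 1.76, p = 2.37e-06, Fisher's exact test). Away from gene ends the shares were 5.44% and 2.73% (odds ratio 2.05, p = 1.72e-13), and at gene ends 7.84% and 8.03% (odds ratio 0.975, p = 1, Fisher's exact test). The direction rested on both depleted libraries, since the odds ratio was 0.781 (p = 0.000273) without depleted replicate 1 and 0.884 (p = 0.0906, exact tests) without depleted replicate 2. It was 2.93 with a score of at least 100. The classes also differed in peak rank. Depletion-only regions had median percentiles of 56.0 and 44.1 in the depleted lists. Control-only regions had 34.7 and 40.1 in the control lists, and the comparison was not adjusted for rank.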

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

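Peaks on contigs outside chromosomes 1 to 19, X and Y, which entered no comparison, were more numerous in the depleted libraries, with 126 in depleted replicate 1 and 108 in depleted replicate 2 against 13 and 26 in the controls (means 117 ± 12.7 and 19.5 ± 9.19, SD, n = 2). A single unplaced contig of chromosome 5 held 39 and 45 of them in the depleted libraries and 0 and 3 in the controls. The SUMO1 list had 0 such peaks.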

How the results depend on the processing

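Equal covered length, the rotation test and widened peaks were tests chosen after the results were seen. The 2-cell-stage call at gene ends held under every alternative run for it (odds ratio 15.0 to 200), and the difference in Jaccard index and the SUMO1 overlap with control H3K27ac stayed on the same side under those run for them. Lists of an equal number of peaks gave 2 lists at gene ends (with naive pluripotency) and 11 passing tests of nearby regions. A score of at least 100 gave 2596 depletion-only regions and 2 lists at gene ends. Windows of 2500 bp gave 185 depletion-only genes and 2 lists. Marked genes as background, which leaves fewer genes tested, gave 5 lists at gene ends and 2 for SUMO1. Equal covered length gave 8601 depletion-only and 710 control-only regions, 1379 and 198 genes, an odds ratio at gene ends of 1.08 (p = 0.515, exact test), 2 lists at gene ends (with Zfp-named genes, depletion-only) and a SUMO1 difference of 8.29 percentage points. Its odds ratio of 0 for control-only regions near primitive endoderm genes (p = 1, exact test) rests on the few such regions left. By construction it kept 60.8% and 100% of the depleted and 25.4% and 27.7% of the control peaks. The rotation test, which keeps neighbours together, left 5 tests of nearby regions past the threshold. The cause of the other changes was not tested.

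Leaving out each H3K27ac library in turn gave 5596 to 13752 depletion-only and 8708 to 14572 control-only regions, 135 to 272 depletion-only and 1732 to 3403 control-only genes, and an odds ratio of 0.781 to 2.00 for SUMO1 on depletion-only against control-only regions. The count of libraries a region must meet is then lower by construction. Replicate numbers as a block gave the same values (5242, 8181, 121, 1610 and -2.67), which pairing cannot alter here. Deviations of same-numbered libraries correlated at 0.0157 over regions and -0.0214 over genes, so the numbers give no sign of pairing. For single lists, 160 results kept direction and call, 53 kept direction alone and 1 reversed. For named genes, 435 results kept the full difference and 85 a smaller one or none, and all 90 results for named regions held. Leaving out a library cannot change these differences, and merging nearby peaks cannot change those of regions. Part of these results therefore could not fail. Unknown read depth limits every count, since a missing peak is not an absent mark.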

Other observations

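Outside the gene lists, SUMO1 was frequent at tRNA genes. The tests of tRNA genes, gene classes, gene families, sex chromosomes, repeated arrays, gene copies, active genes and wider control peaks were chosen only after the results were seen. Of 408 tRNA genes, 243 (59.6%, 95% interval 54.6 to 64.4) had a SUMO1 peak within 1 kb, against 5.06% of all annotated genes (odds ratio 30.5, permutation by rotation p = 4e-05, the smallest it can give, adjusted p = 0.0001 over 30 tests). Peaks near tRNA genes made up 2.32% of SUMO1 peaks, against 0.0325% after shifts (p = 0.002, the smallest they can give, permutation test). H3K27ac lay at 213 and 169 tRNA genes in the depleted libraries and 197 and 191 in the controls. Of the 408, 16 were depletion-only (3.92% against 0.773% of all annotated genes, odds ratio 5.42, permutation by rotation, adjusted p = 0.00375) and 14 control-only (3.43% against 5.19%, adjusted p = 0.253). Of the 184 tRNA genes with H3K27ac in both controls, 166 also had SUMO1 (odds ratio 17.5, permutation by rotation p = 0.00490).

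Pseudogenes were depletion-only more often than annotated genes at large (134 of 9944, 1.35% against 0.773%, permutation by rotation p = 4e-05, the smallest it can give, adjusted p = 0.0001), and 179 were control-only (1.80% against 5.19%). They were marked in 6.15% and 4.92% in the depleted libraries and 6.10% and 6.13% in the controls. Of 1108 olfactory receptor genes, 0 had SUMO1, and of 47 Pramel genes, 8 were depletion-only, among them Pramel19 and Pramel20. Of 19 Ugt genes, 7 were depletion-only through 2 regions (rotation adjusted p = 0.207 by permutation), 6 of them Ugt1a genes. The protocadherin genes Pcdhga and Pcdhgb were control-only in 9 of 12 and 6 of 6 members, through 1 region. In 2064 tests over 688 families, 8 passed by Fisher's exact test and 0 by both this and rotation, so these families stay descriptions. For olfactory receptor genes (SUMO1 and control-only) and vomeronasal receptor genes (SUMO1), permutation by rotation gave p = 9.14e-05, the smallest it can give. Over so many tests the adjusted p was still 0.0629, so rotation cannot decide these cases. On chromosome X, 17.7% of regions were depletion-only against 10.4% on autosomes (odds ratio 1.86, p = 2.85e-19, Fisher's exact test, neighbouring regions treated as independent), and 8.79% were control-only against 17.0%.

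The gain of H3K27ac at 2-cell-stage genes was weighed first. Neighbouring genes counted as independent would lose the call under the permutation test by rotation, which gave p = 9.14e-05, the smallest it can give, and the call also stood at equal covered length (odds ratio 15.0). Repeated arrays were defined by like names of neighbouring genes. Names of the Gm and LOC type were left out, so the Gm genes of the chromosome 12 stretch counted as outside arrays. In arrays so defined, 5 of 15 list members were depletion-only (33.3%), against 0.847% of the other genes (p = 1.74e-07, Fisher's exact test). Of all genes outside arrays, list members included, 77 of 17268 (0.446%) were depletion-only. The remaining depletion-only list members lay outside arrays so defined. An equal gain at all such arrays is argued against, the Ugt and Pramel genes above aside, but Gm arrays were not covered. The depletion-only members lay in 9 loci over 1 Mb apart. Distance cannot decide whether a gain at a single copy was spread over near-identical copies. Usp17l genes lay in separate loci of these, as did Pramel genes, and sequence identity was not examined. Ubc9 loss may bring H3K27ac to these loci, a hypothesis found and tested on the same data. A doxycycline time is recorded for the depleted libraries alone, so on these records doxycycline itself and Ubc9 loss cannot be told apart. Whether every cell or a larger share of 2-cell-like cells carried the mark was not tested, nor were repeats and mappability at these copies.

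The excess of control-only over depletion-only genes was weighed second. Wider control peaks that reach gene ends are argued against as the whole cause, since 88.1% of control-only genes stayed so with widened peaks, though 0 of the 16 top-ranked ones did. Lower peak recovery in the depleted libraries stays open, because 47.9% of genes in the lowest of 4 equal groups by control peak rank were control-only against 3.18% in the highest, a ratio of 15.1. Different covered length is not decided, because equal length (a ratio of control-only to depletion-only genes of 0.144) removed mostly control peaks by construction. The ratio was 14.7 at equal peak number and 20.2 with a score of at least 100. That score cut can raise the ratio by itself, since median scores were 130 and 111 in the depleted and 218 and 206 in the control lists. A loss of H3K27ac with Ubc9 may also contribute and remains untested apart from these.

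SUMO1 peaks were most frequent on chromosomes 6 and 8, with 0.718 per coding gene against 0.383 on the other autosomes and 0.0611 on X. More active genes on these chromosomes are argued against as the whole cause in this library. Among genes marked in both controls, 23.2% had SUMO1 there against 10.5% elsewhere (odds ratio 2.57, p = 6.91e-25, Fisher's exact test). Both chromosomes were picked for their many SUMO1 peaks, which raises this share too, and the p-value takes no account of that choice. Extra copies of both chromosomes in the wild-type culture were neither excluded nor shown. Of their 26 bins of 10 Mb, 84.6% lay above the median bin of the other autosomes, but the chromosomes were picked for their many peaks, which largely sets this share. The median bin of chromosome 11 held 52.5 peaks, more than the 45.5 of chromosome 6.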
